A study of Zea mays
Phyllachora maydis with 12 samples.

How the data were processed

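Leaf RNA of the maize inbred line B73 was sequenced from 12 libraries in 4 groups of 3, which crossed exposure to a field infested with the tar spot fungus Phyllachora maydis (exposed or non-exposed) with the day of sampling (10 or 24). Per the labels' protocols, each sample was made from 5 leaf disks, and poly(A) RNA was made into libraries with a stranded kit. Days were counted from the start of the exposure. All exposed libraries carried the label of batch 1 and all non-exposed libraries that of batch 2. The batch was therefore the same division as the exposure, no fit with batch as a term could be had, and within each batch there was no exposure comparison to compute.

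The deposited table held whole-number counts of reads per gene identifier, with no normalization. Per the submitters' processing notes, cutadapt, HISAT2, HTSeq, DESeq2 and DESeq were used by the authors; their versions, the genome build, the annotation and the strand setting were not given in the sources used here. How reads matching several near-identical genes were counted was likewise not given, so that values of genes with near-identical copies are uncertain. Without a stated strand setting, reads of a gene and an antisense partner could not be told apart.

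The table listed 44303 identifiers, all with the prefix Zm00001eb, and 9123 of them had no read in any library. It held 0 identifiers of another kind, so the share of reads assigned to fungal genes, a result fixed in advance, was not given. The reference gene table used here (assembly Zm-B73-REFERENCE-NAM-5.0) matched 0 of these identifiers. Gene names, coordinates, the 31 gene lists fixed in advance, and checks of gene length and GC content could therefore not be used here. The rule for named genes fell back, as fixed in advance, to 2 identifiers in each direction per comparison. These had the largest log2 fold changes among genes past the threshold with a mean of at least 1 log2 CPM (reads of a gene scaled to a fixed library total) over the 12 libraries. No overlap between the libraries compared was also required, except for the interaction.

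Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr, which left 25411 genes and removed 18892. Libraries were scaled with TMM factors, a robust quasi-likelihood model with 4 group means was fitted to all 12 libraries, and 5 contrasts were tested with the quasi-likelihood F-test. These were exposed against non-exposed plants at each day, day 24 against day 10 within each exposure, and the difference of the exposure effect between days (the interaction). P-values were adjusted with the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called; all adjusted p-values below come from this test unless another tool is named. Log2 CPM values for plots and correlations used a prior count of 2. Group values are given as CPM ± SD of 3 libraries. The SE of a log2 fold change was derived as its absolute value divided by the square root of the F statistic. It restates the test and is not a separately fitted standard error, so it may describe poorly the uncertainty of genes with few reads in a group. The labels name replicates but do not say that they came from separate plants, so that p-values measure only the spread between these samples, which may be technical.

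Total counts ranged from 42090969 to 109636248 per library. Taking 3 counts as the limit that a count of 0 allows, a gene with no read lay under 0.0713 CPM in the shallowest library and under 0.0274 CPM in the deepest; these limits and the 95% exact (Clopper-Pearson) intervals on ratios cover counting error only. The model's biological coefficient of variation was 0.312. The fit was tested on simulated data with known changes in 200 genes, drawn from the real means, depths and dispersions. The changed genes were taken from those with a mean of at least 0 log2 CPM. With so few changed genes the adjustment of p-values is stricter than in the real comparisons, where many more genes were called. The recovered shares therefore hold for the simulation and are not the sensitivity of the real fits. In the simulated exposure comparison at 10 days (25065 genes), 81.8% of 4-fold, 41.8% of 2-fold and 0% of 1.5-fold changes were recovered, and at 24 days (25038 genes) 78.8%, 43.3% and 2.99%. For the simulated change with time these shares were 83.3%, 43.3% and 2.99% in exposed plants (25036 genes) and 89.4%, 49.3% and 1.49% in non-exposed plants (25034 genes). For the simulated interaction (25044 genes) they were 62.1%, 10.4% and 1.49%. False calls made up 2.27% to 9.26% of the calls in these simulations.

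Gene groups of 3 kinds were described, none of which needs gene names. The first were quartiles of mean log2 CPM over all libraries. The second were the 100 genes with the highest mean CPM, not log2 CPM, over all libraries. The third, found after the data were examined, were runs of consecutive identifiers: windows of 20 tested genes in identifier order in which at least 16 were called lower in exposed plants at 24 days, merged and trimmed. Shares of counts were compared by two-sided exact permutation tests, whose smallest p with 3 against 3 libraries is 0.1.

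Alternatives fixed before the data were examined were RLE factors, upper-quartile factors, library totals alone, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, a fit to the compared libraries only, DESeq2 1.42.0, limma-voom (limma 3.58.1), an absolute log2 fold change of at least 1, an adjusted p under 0.01, and leaving out each library in turn. Fits without the identifier runs, and without these runs and the 100 most abundant genes, were added after the data were examined. Figures were drawn with matplotlib 3.10.9.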

Results

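Leaves of B73, the maize inbred line of the reference genome, were compared between plants placed in a field with a high load of the tar spot fungus Phyllachora maydis and plants never placed there. Plants were grown for 30 days, the exposed ones then spent 10 days in the field before returning to a greenhouse, and leaf disks were taken 10 and 24 days after the exposure began. Each of the 4 groups had 3 libraries. Total counts per library were 57878364 to 73523081 in non-exposed and 77374781 to 109636248 in exposed plants at 10 days. At 24 days they were 42090969 to 58223743 in non-exposed and 44097321 to 59459472 in exposed plants. Exposure in this design combined the inoculum with everything else that differed between field and greenhouse, and the labelled batch separated the libraries in the same way as the exposure. The 2 could not be told apart in any comparison of exposed with non-exposed plants.

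Libraries of a group resembled each other more than those of any other group. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.945 to 0.977 within groups and at most 0.936 between them. The first principal component held 51.1% of the variance and separated exposed from non-exposed libraries at both days. Components 2 and 3 held 15.9% and 13.3%. Measured as the root mean square log2 difference between group means, exposed and non-exposed plants lay 1.47 apart at 10 days and 1.69 apart at 24 days. The 2 days lay 1.21 apart in exposed and 1.03 apart in non-exposed plants. Replicate pairs all differed by more than sampling noise, with a chi-square per gene of 35.8 or more.

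**Figure D1:**
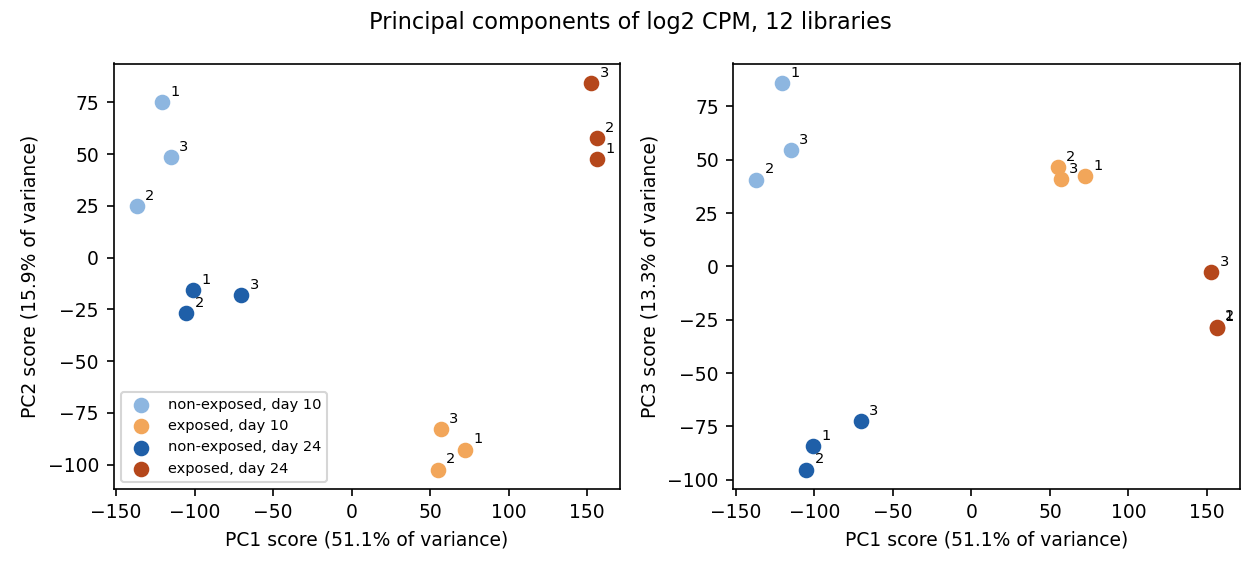
Scores of the 12 libraries on principal components 1 and 2 (left) and 1 and 3 (right), computed from log2 CPM; each point is a library, colours are groups and digits are replicate numbers. Component 1 (51.1% of variance) ranks the non-exposed libraries below 0 and the exposed libraries above 0, with the exposed libraries of day 24 farthest out.

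The first non-exposed library of 10 days stood apart within its group. In it, 564 genes were above 1 CPM and over 8 times their level in both other libraries of the group, against 3 to 73 such genes in each of the other 11 libraries. After all libraries were thinned to 42090969 reads, the number was 550, against at most 73. These genes took 0.544% of its counts and 0.0183% and 0.0246% of those of the other libraries of its group. Of the 564 genes, 182 passed the low-count filter, and 90 of these were called lower and 4 higher in exposed plants at 10 days.

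**Figure D2:**
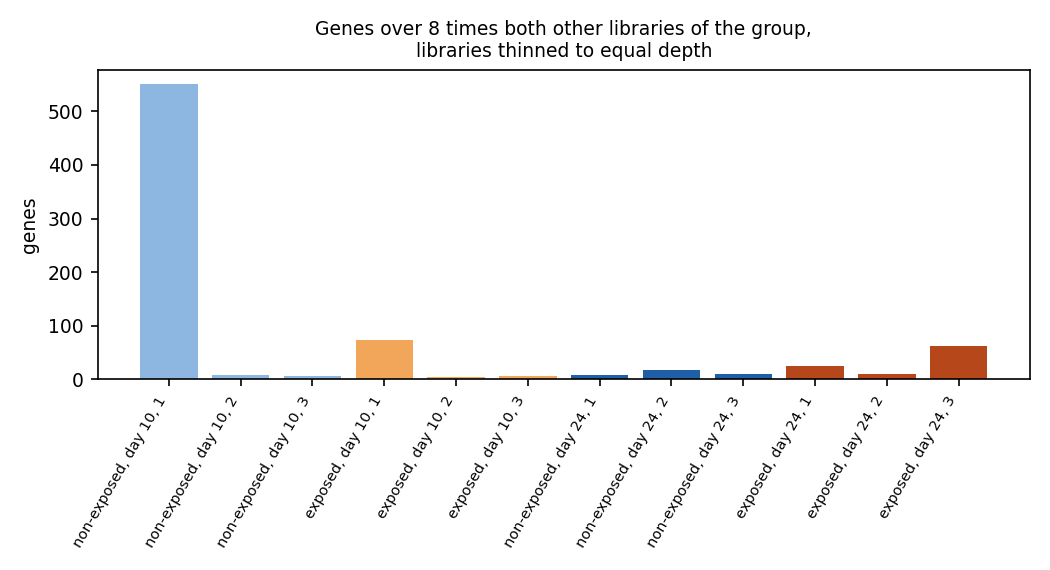
Number of genes (vertical axis) above 1 CPM and over 8 times their level in both other libraries of the same group, per library, after thinning to 42090969 reads; bars are single libraries. The first non-exposed library of day 10 had 550 such genes and no other library more than 73.

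At 10 days, when the exposed plants came to the end of their time in the field, 13367 of 25411 tested genes (52.6%) differed between exposed and non-exposed plants. Of these, 6602 were higher and 6765 lower in exposed plants, and the median absolute log2 fold change of the called genes was 1.14. Large changes were mostly decreases: 4802 genes were at least 2-fold lower and 2673 at least 2-fold higher, and 1392 were at least 8-fold lower against 481 at least 8-fold higher. Zm00001eb002280 rose from 0.0526 ± 0.0528 CPM (10 reads in the group) to 12.9 ± 7.85 CPM (SD, n = 3 per group; log2 fold change 7.94 ± 0.754 SE, adjusted p = 1.61e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Its log2 fold change was 8.78 and 7.36 without the second and the third non-exposed library and 7.35 without the second exposed library. Zm00001eb161370 rose from 0.67 ± 0.487 to 137 ± 142 CPM (log2 fold change 7.71 ± 1.06 SE, edgeR adjusted p = 0.000223), with log2 fold changes of 6.41 without the third exposed library, which held 32214 of the 43616 reads, and 8.38 without the second non-exposed library. Zm00001eb170440 fell from 24.5 ± 8.09 to 0.125 ± 0.0972 CPM (log2 fold change -7.53 ± 0.704 SE, edgeR adjusted p = 1.47e-05). Zm00001eb285360 fell from 205 ± 321 to 0.198 ± 0.154 CPM (log2 fold change -10.04 ± 1.83 SE, edgeR adjusted p = 0.0013). Its non-exposed level came mostly from the library that stood apart (44092 reads against 330 and 2275), and without that library its log2 fold change was -6.66; without the third exposed library it was -10.71.

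Direction at 10 days differed with abundance. In the quartile of genes with the lowest mean level, 1947 genes were lower and 556 higher in exposed plants (median log2 fold change -0.87). In the quartile with the highest level, 2872 were higher and 1167 lower (median 0.28). Both medians kept their sign under all 4 scalings. Without the first non-exposed library of 10 days, 1637 genes of the lowest quartile were lower and 480 higher (median -0.67). Among the 100 most abundant genes the direction was the opposite of that of their quartile, with 49 lower and 12 higher (median -0.54). Their share of all counts was 22.2% ± 1.9 in non-exposed and 15.3% ± 1.7 in exposed plants (SD, n = 3; exact permutation p = 0.1, the smallest this design allows). Under upper-quartile factors the comparison gave 5031 genes higher and 8014 lower (38.6% higher, against 49.4% with TMM factors), and the median log2 fold change of all genes moved from -0.03 to -0.19.

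At 24 days, after the return to the greenhouse, 13814 genes (54.4%) differed between exposed and non-exposed plants, 7161 higher and 6653 lower in exposed plants, with a median absolute log2 fold change of 1.20. At least 2-fold changes numbered 3529 higher and 4502 lower, and at least 8-fold changes 1046 higher and 1362 lower. Zm00001eb168350 rose from 0.383 ± 0.22 to 147 ± 200 CPM (SD, n = 3 per group; log2 fold change 8.63 ± 1.44 SE, edgeR adjusted p = 0.000619). Zm00001eb014010 rose from 0.16 ± 0.194 to 97.2 ± 135 CPM (log2 fold change 9.24 ± 2.36 SE, edgeR adjusted p = 0.00762). Both were highest in the third exposed library, without which their log2 fold changes were 6.42 and 6.93. That of Zm00001eb014010 was also 8.63 and 10.99 without the first and the third non-exposed library. Zm00001eb437100 fell from 133 ± 183 to 0.0591 ± 0.0711 CPM (log2 fold change -11.09 ± 2.47 SE, edgeR adjusted p = 0.00359), and its log2 fold change was -8.82 without the second non-exposed library and -12.73 without the third exposed library. Zm00001eb441950 fell from 48.5 ± 47.5 to 0.0105 ± 0.0181 CPM (edgeR adjusted p = 0.00372). With only 2 reads in the exposed group, its ratio was 3750, with a 95% counting interval of 1040 to 31000. Its fitted log2 fold change, -11.80, was -10.62 without the second non-exposed library and -14.67 without the first exposed library. Zm00001eb437100 and Zm00001eb441950 both belonged to the runs of identifiers described next, and their values are uncertain if they share reads with near-identical copies.

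In 3 runs of consecutive identifiers, found after the data were examined, most tested genes were lower in exposed plants; the other 6191 of the 6653 genes lower at 24 days lay outside them. The runs went from Zm00001eb261890 to Zm00001eb262510 (59 tested genes), from Zm00001eb263240 to Zm00001eb264050 (78 genes) and from Zm00001eb434930 to Zm00001eb443020 (359 genes). Of these 496 genes, 428 were lower and 8 higher at 10 days (median log2 fold change -2.56), and 462 were lower and 6 higher at 24 days (median -5.26). The runs were defined by calls at 24 days, so the values of that day, and their excess over those of 10 days, were partly fixed by the choice. The 3 runs had nearly equal medians, -2.61, -2.69 and -2.53 at 10 days and -5.26, -5.41 and -5.25 at 24 days. The fullest window of 20 genes had all 20 lower, against at most 17 in 1000 shuffles of the gene order. No run of genes higher in exposed plants was found by the same rule (fullest window 15, against at most 17 in the shuffles). The run genes took 1.19% ± 0.959 of all counts in non-exposed and 0.181% ± 0.0362 in exposed plants at 10 days, and 1.49% ± 1.41 and 0.062% ± 0.00841 at 24 days (SD, n = 3). The second non-exposed library was the highest of its group at both days, at 2.3% and 3.12%.

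The 100 most abundant genes were also mostly lower at 24 days, with 75 lower and 5 higher (median log2 fold change -1.58). Their share of all counts was 25.1% ± 0.79 in non-exposed and 11.9% ± 0.48 in exposed plants (SD, n = 3; exact permutation p = 0.1, the smallest this design allows). Their median was below 0 under all 4 scalings, -1.28 with library totals alone. In the quartile of genes with the lowest level, 1233 were higher and 1323 lower (median -0.16), and the sign of this median turned with library totals alone (0.13). With library totals alone 10136 genes were higher and 4888 lower (67.5% higher, against 51.8% with TMM factors), and the median of all genes moved from 0.02 to 0.33.

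**Figure D3:**
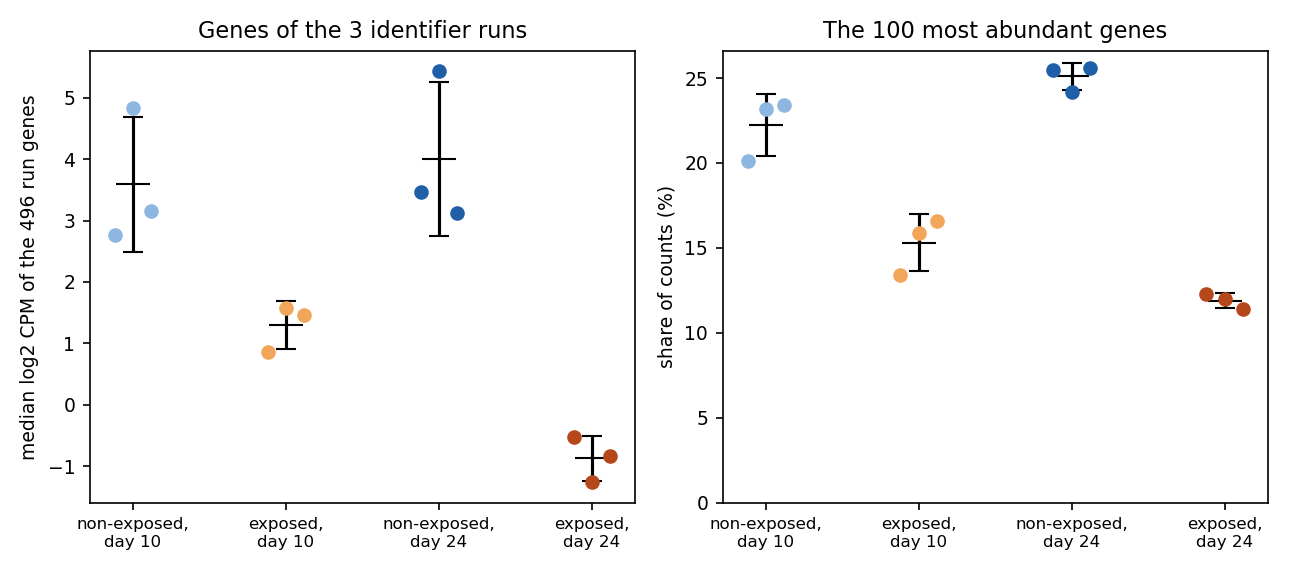
Median log2 CPM of the 496 genes of the 3 identifier runs (left) and share of counts in percent taken by the 100 most abundant genes (right), for each library by group; bars are the mean ± SD of 3 libraries. Both quantities are lower in every exposed library than in every non-exposed library of the same day, and lowest in the exposed libraries of day 24. The run genes were chosen by their calls at day 24, which partly fixes their values there.

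Exposure calls at both days shared many genes. In the same direction, 7439 genes were called at both days: 3670 higher and 3769 lower, against 1860.5 and 1771.2 for independent lists. These made up 55.7% of the genes called at 10 days. The 2 comparisons had no library in common, but in both the labelled batch differed in the same way as the exposure. A constant batch difference could therefore also give shared calls in the same direction and correlated log2 fold changes. Across genes, Pearson's r of the log2 fold changes was 0.467 and Spearman's rho 0.484. In opposite directions, 1068 genes were called: 578 lower at 10 and higher at 24 days, against 1906.4 for independent lists, and 490 higher at 10 and lower at 24 days, against 1728.5. At either day 18674 genes (73.5%) were called, and 6737 at neither.

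**Figure D4:**
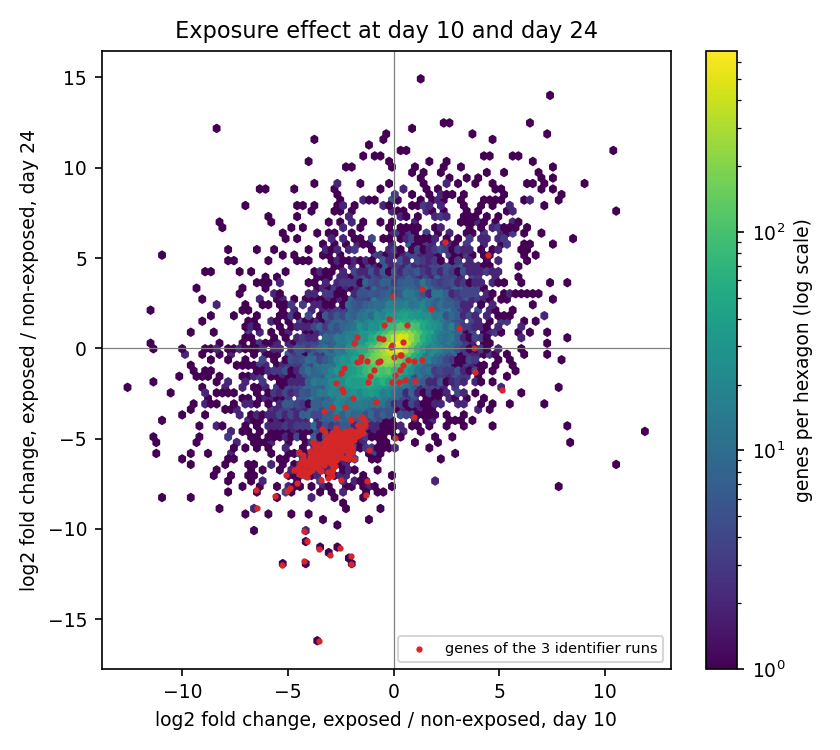
Log2 fold change of exposed over non-exposed plants at day 10 (horizontal axis) and day 24 (vertical axis) for the 25411 tested genes; hexagon colour is the number of genes on a log scale and red points are the 496 genes of the identifier runs. Pearson's r across genes was 0.467, and most run genes lie in a separate cloud at low values of both axes.

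The exposure effect differed between days in 8183 genes (32.2%) by the test of the difference itself, 4100 with a higher and 4083 with a lower effect at 24 days. All 1068 genes called in opposite directions were among them. Of the 7439 genes called in the same direction at both days, 1760 were among them, and 1544 of the 2913 genes called higher at 24 days alone. Zm00001eb161370 was higher in exposed plants at 10 days and below the non-exposed level at 24 days (131 ± 95.4 CPM in non-exposed and 0.688 ± 0.146 CPM in exposed plants; log2 difference of the effects -15.29 ± 1.49 SE, edgeR adjusted p = 0.000134). The difference was -13.99 without the third exposed and -15.96 without the second non-exposed library of 10 days, and -14.51 without the second non-exposed library of 24 days. Zm00001eb002280 also reversed, with 18.1 ± 2.59 CPM in non-exposed and 3.97 ± 1.63 CPM in exposed plants at 24 days (log2 difference -10.14 ± 0.92 SE, edgeR adjusted p = 7.79e-05; -10.97 and -9.54 without the second non-exposed and the second exposed library of 10 days). In the other direction, Zm00001eb305230 was at 19.7 ± 12.4 CPM in non-exposed and 0.279 ± 0.393 CPM in exposed plants at 10 days, and at 0.744 ± 0.125 and 10.1 ± 7.5 CPM at 24 days (log2 difference 9.87 ± 1.47 SE, edgeR adjusted p = 0.000993). Its difference was 12.27 without the third exposed library of 10 days, 9.24 without the first non-exposed library of 10 days and 9.14 without the third exposed library of 24 days. Zm00001eb014010 had the largest positive difference among the identifiers that met the rule (log2 difference 11.82 ± 2.85 SE, edgeR adjusted p = 0.0115). It was 9.10 without the first non-exposed and 13.38 without the first exposed library of 10 days. Without the third exposed library of 24 days it was 9.51, and without the first and the third non-exposed library of that day 11.20 and 13.55. With library totals alone, 6380 differences were positive and 2442 negative (72.3% positive, against 50.1% with TMM factors), and the median of all genes moved to 0.31.

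From 10 to 24 days, 8727 genes (34.3%) changed in exposed plants, 4287 higher and 4440 lower at 24 days. This period also held their return from the field to the greenhouse, so age and that move cannot be told apart here. Large changes were more often increases, with 2567 genes at least 2-fold higher and 1890 at least 2-fold lower, and 771 at least 8-fold higher against 305 at least 8-fold lower. Of the 496 run genes, which were chosen by their calls at 24 days, 217 fell and 2 rose (median log2 fold change -2.13). Of the 100 most abundant genes, 54 fell and 7 rose (median -0.69, and below 0 under all 4 scalings). Zm00001eb078730 rose from 0.631 ± 0.075 to 61.9 ± 40.1 CPM (SD, n = 3 per group; log2 fold change 6.61 ± 0.971 SE, edgeR adjusted p = 0.000768), with a log2 fold change of 5.94 without the third library of 24 days. Zm00001eb301260 rose from 0.0967 ± 0.0605 to 8.87 ± 3.54 CPM (log2 fold change 6.42 ± 0.833 SE, edgeR adjusted p = 0.000374). Zm00001eb161370 fell from 137 ± 142 to 0.688 ± 0.146 CPM (log2 fold change -7.64 ± 1.06 SE, edgeR adjusted p = 0.000543), with a log2 fold change of -6.34 without the third library of 10 days. Zm00001eb441950, a run gene, fell from 4.87 ± 5.89 CPM to 0.0105 ± 0.0181 CPM, or 2 reads in the group (ratio 421, 95% counting interval 116 to 3480; edgeR adjusted p = 0.0362). Its fitted log2 fold change, -8.48, was -6.82 without the third library of 10 days and -11.36 without the first library of 24 days. Its call was lost in 6 of the 12 fits that left out 1 library, where the adjusted p was 0.0504 to 0.109. With library totals alone, 5238 genes were higher and 3363 lower (60.9% higher, against 49.1% with TMM factors).

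In non-exposed plants 6651 genes (26.2%) changed from 10 to 24 days, 3200 higher and 3451 lower at 24 days. At least 2-fold changes numbered 1396 higher and 1729 lower. Of the 100 most abundant genes, 29 were higher, 5 lower and 66 not called (median log2 fold change 0.43, and above 0 under all 4 scalings). Of the 496 run genes 4 rose and 4 fell (median 0.47). Zm00001eb002280 rose from 0.0526 ± 0.0528 to 18.1 ± 2.59 CPM (SD, n = 3 per group; log2 fold change 8.44 ± 0.763 SE, edgeR adjusted p = 0.000107), with a log2 fold change of 9.27 without the second library of 10 days. Zm00001eb301260 rose from 2.14 ± 1.03 to 481 ± 318 CPM (log2 fold change 7.80 ± 0.777 SE, edgeR adjusted p = 0.000237), and its change did not differ detectably from that in exposed plants (edgeR adjusted p of the difference = 0.371). Zm00001eb165610 fell from 243 ± 313 to 1.55 ± 0.504 CPM (log2 fold change -7.28 ± 1.1 SE, edgeR adjusted p = 0.00174), and its log2 fold change was -5.30 without the first library of 10 days. Zm00001eb014010 fell from 18.4 ± 27.1 to 0.16 ± 0.194 CPM (log2 fold change -6.84 ± 2.24 SE, edgeR adjusted p = 0.0473). That call was lost in 8 of the 12 fits that left out 1 library, with an adjusted p of up to 0.199, reached without the first library of 10 days, where the log2 fold change was -4.13. It was -6.22 and -8.58 without the first and the third library of 24 days. The number of called genes was 4177 without the second library of 24 days, 2242 higher and 1935 lower. Without the first library of 10 days 2782 were higher and 2564 lower. Of the fits that left out a non-exposed library, only that without the second library of 10 days kept more decreases (2666 higher, 3129 lower). All fits that left out an exposed library kept them, so the small excess of decreases was not stable. With library totals alone, 2048 genes were higher and 5436 lower (27.4% higher, against 48.1% with TMM factors), and the median of all genes moved from -0.02 to -0.20.

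Changes with time had little in common between exposed and non-exposed plants. The change in exposed plants also held the return from field to greenhouse, a move that non-exposed plants did not make. The 2 sets are therefore not the same time course under 2 treatments. Across genes, Pearson's r of the 2 sets of log2 fold changes was -0.000758 and Spearman's rho -0.0224, with no library shared. Of the genes called in both, 648 were higher and 707 lower at 24 days in both, against 539.86 and 602.98 for independent lists. In opposite directions, 709 rose in exposed and fell in non-exposed plants and 734 did the reverse, against 582.21 and 559.13.

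**Figure D5:**
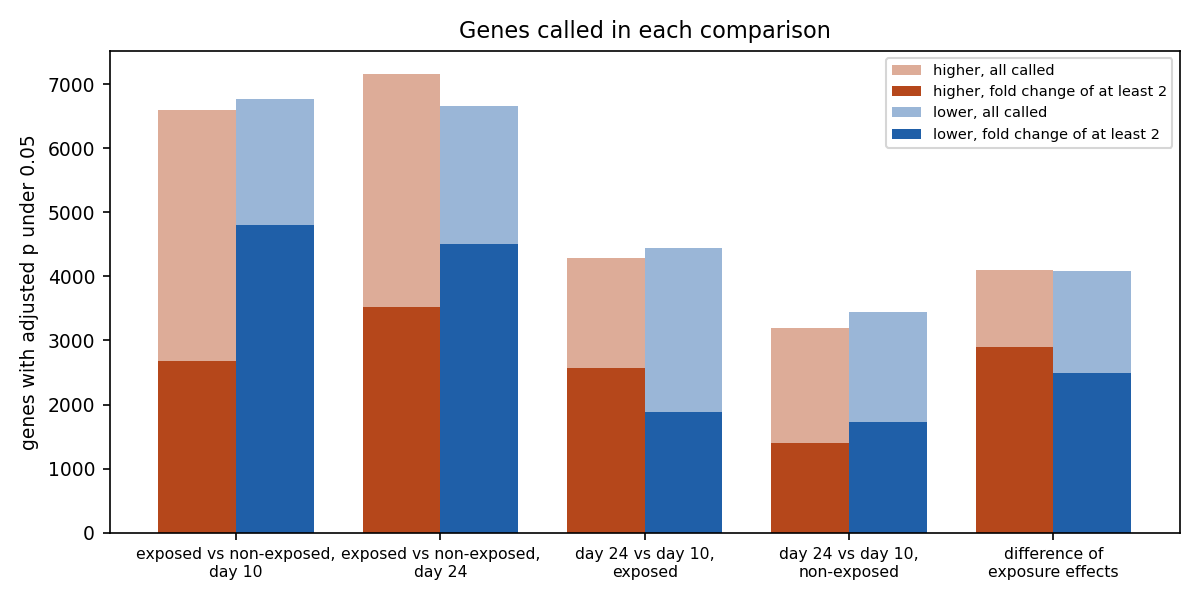
Number of genes (vertical axis) with adjusted p under 0.05 in the 5 comparisons, higher and lower in the first-named group; pale bars are all called genes and dark bars those with a fold change of at least 2. The exposure comparisons called 13367 and 13814 genes, those between days 8727 and 6651, and the difference of exposure effects 8183.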

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

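Splits of 3 against 3 libraries were tested as planned before their results were seen; the splits for the interaction were drawn again, and the tests of technical explanations in this part chosen, after results were seen.

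The size of the exposure effect differed between 10 and 24 days in 8183 genes, and this was picked out because the difference itself passed the interaction test. Of 100 splits of the libraries within each day, drawn from 200 possible ones with the real one included, 2 called as many genes: the real one and, with 15966 genes, the one that exchanged the exposure labels of 1 day and so tested the sum of the 2 effects. The other 98 mixed exposed with non-exposed libraries, had a dispersion at least 2.48 times the real one and called at most 5573 genes. Because the exposure effect entered their spread, these splits do not decide whether chance assignment could give the count. Among the single identifiers, the interaction was called for Zm00001eb002280 (edgeR adjusted p = 7.79e-05) and Zm00001eb161370 (0.000134), which were higher in exposed plants at 10 days and lower at 24 days. It was called in the other direction for Zm00001eb305230 (0.000993), Zm00001eb078730 (0.000929) and Zm00001eb165610 (0.00103), which were lower in exposed plants at 10 days and higher at 24 days. For Zm00001eb170440 (0.00125) the decrease was smaller at 24 days, with log2 fold changes of -7.53 and -2.46. Zm00001eb285360 (0.0129) was called lower at 10 days and not at 24 days. Zm00001eb014010 (0.0115) and Zm00001eb168350 (0.0123) were called higher at 24 days and not at 10 days. In non-exposed plants at 10 days, all of these but Zm00001eb002280 and Zm00001eb161370 were highest in the library that stood apart, among them Zm00001eb014010 (3796 reads against 24 and 352) and Zm00001eb078730 (583 against 42 and 87). In exposed plants at 24 days, Zm00001eb014010, Zm00001eb168350, Zm00001eb078730 and Zm00001eb305230 were highest in the third library.

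A difference in over 50% of tested genes between exposed and non-exposed plants may have technical sources, since the labelled batch followed the exposure. A batch difference that is constant on the log scale and acts alone forbids a change of the effect between days. The 8183 genes with such a change, 6477 to 8152 when 1 library was left out, argue against it as the whole cause for those genes. A constant batch difference added to an exposure effect would leave the interaction unchanged, so part of their difference may still come from the batch. For the 7439 genes changed in the same direction at both days, 76.3% had no called difference between days. For these a constant batch difference and an exposure effect cannot be told apart, because no exposed library shared a batch with a non-exposed one. A batch difference that itself varied between days was not tested and stays open. A few genes did not take most of the counts. The share of the 100 most abundant genes was highest in non-exposed plants at 24 days, at 25.1% ± 0.79 (SD, n = 3). The identifier runs took at most 3.12% of any library. Without trimmed factors, taking the identifier runs and the 100 most abundant genes out of the library totals moved the median log2 fold change of the other genes by -0.26 at 24 days, and 82.4% of their 14481 calls stayed in the same direction. At 10 days 89.3% stayed, and in the fits that left out 1 library at least 79.5% at either day. Such a removal moves all other genes by nearly the same amount. At 24 days that amount was small beside the median absolute log2 fold change of called genes, 1.20. Most calls were therefore bound to stay, and the shares kept are no further test. The balance of directions did depend on the runs and the 100 most abundant genes, with 10118 higher and 4363 lower at 24 days before and 7566 and 5831 after. Exposure to the fungus and the other conditions of the field stay open as biological explanations, and this design does not separate them.

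For the comparisons of 3 against 3 libraries, 10 splits exist, which is too few for a share under 0.05. The real split called 13367 genes for exposure at 10 days, 13814 for exposure at 24 days, 8727 for time in exposed plants and 6651 for time in non-exposed plants. In each of these comparisons 1 of the 10 splits, the real one, called as many, and the highest of the others called 0 genes with edgeR. At an unadjusted p under 0.05 the highest of the others called 1401, 1041, 1224 and 1760 genes, against 14842, 15140, 11416 and 9973 in the real split. No other tool was run on these splits. Every split but the real one put libraries of both groups into each of its sides. The real difference thus entered its spread and lowered its count, so these splits do not decide whether chance assignment could give the counts.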

How the results depend on the processing

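The fits without the identifier runs, and without the runs and the 100 most abundant genes, were chosen after the data were examined; the other settings were planned. With an absolute log2 fold change of at least 1, a stricter rule by construction, 7475 genes were called for exposure at 10 days, 8031 at 24 days, 4457 for time in exposed plants, 3125 for time in non-exposed plants and 5391 for the interaction, with 3729 shared in the same direction and 383 in opposite directions. With an adjusted p under 0.01 the counts for time were 4983 and 2944 and for the interaction 4244. Leaving out 1 library at a time gave 11640 to 13421 genes at 10 days, 11763 to 14407 at 24 days, 6636 to 9482 and 4177 to 6641 for time in exposed and non-exposed plants, and 6477 to 8152 for the interaction. It gave 6454 to 7448 for the shared calls and 842 to 1045 for the opposite ones. Only the 4177, without the second non-exposed library of 24 days, lay more than 1.5 times from its full count. For the 5 counts of called genes, the other planned and added settings gave values within 1.5 times, with no fit to the compared libraries only for the interaction, which uses all of them. The shared and opposite calls were also recomputed with RLE factors, the block and DESeq2, within 1.5 times. DESeq2 called 14202, 14515, 9945, 8146 and 9647 genes in the 5 comparisons and limma-voom 13826, 12964, 8664, 5979 and 7468. The single identifiers were followed only with RLE factors, library totals alone, the 1 CPM filter, the block, DESeq2 and each library left out. Of 338 such fits, 324 kept direction and call, 14 lost the call in 2 identifier and comparison pairs when a library was left out, and 0 reversed. The identifiers were picked from the same data for large changes and, outside the interaction, for no overlap of libraries. These numbers therefore say little about how stable other calls are. DESeq2 gave no adjusted p for Zm00001eb168350 at 24 days and Zm00001eb165610 with time in non-exposed plants, and these fits are not among the 338.

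Whether replicate numbers pair the libraries was not settled. The 18 same-numbered pairs had correlations of deviations from -0.0608 to 0.249 (median 0.066), 5 of them over 0.1. The 36 other pairs had a median of -0.042 and a highest value of 0.127. Of 12 libraries, 10 correlated best with their own number, a hint of pairing from the data only. With the replicate number as a block, 13205, 13647, 8713, 6359 and 8179 genes were called, with 7375 shared and 1051 opposite. At this depth a gene without reads could lie anywhere under 0.0713 CPM in the shallowest library. Simulated 2-fold changes were recovered in 41.8% of genes at 10 days against 81.8% of 4-fold changes. These shares come from data with few changed genes and are not the sensitivity of the real fits. The tests of gene lists and the share of fungal reads, with their alternatives, were not run, because no identifier could be matched to a name and the table held no fungal identifier.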

Other observations

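All tests of explanations in this part were chosen after the patterns were seen.

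Genes without any read in one group and with at least 1 CPM in each library of the other were few: 12 had reads only in non-exposed and 1 only in exposed plants at 10 days, and 2 and 23 at 24 days.

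The 3 identifier runs had median log2 fold changes below 0 in exposed plants at both days, and of their 496 genes 103 had a lower and 1 a higher effect at 24 than at 10 days by the interaction test, while 392 had no called difference. The median difference between days was -2.59 on the log2 scale. Over library medians, with libraries taken as unpaired, its 95% interval was -4.91 to -0.263 (SE 1.01). Its width assumed equal spread in all groups. The SD of library medians was 1.1 and 1.25 in non-exposed plants at 10 and 24 days, and 0.391 and 0.373 in exposed plants. Whether 0 is excluded is therefore not settled. The interval reached into the range of -0.5 to 0.5 allowed for a constant batch difference, by a bar set after the value was seen. The genes were also chosen by their effect at 24 days, and Zm00001eb441950 and Zm00001eb437100 had no called difference (edgeR adjusted p = 0.108 and 0.0645). A constant batch difference therefore stays open for the runs as a whole. One factor per library held 90.2% of the within-group variance of the run genes, against at most 48.1% in 100 random gene sets. Such a pattern is consistent with one shared source of reads present in varying amounts, such as a family of near-identical sequences, but joint regulation of these genes would give it too, and a response to exposure stays open.

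The genes high only in the first non-exposed library of 10 days did not follow from depth: at equal depth it had 7.53 times as many as the next library. An exchange with a library of another group is argued against by its mean correlation, 0.0522 higher with its own group than with any other. Of the 564 genes, 76.4% were also under an eighth of its level in each of the other 11 libraries, and 175 had at most 1 read in each of them. This is consistent with RNA of a tissue or state sampled in that library alone, a hypothesis that could be checked once the identifiers are named; a difference between plants stays open.

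A hypothesis was that exposed plants at 10 days were shifted along the change that non-exposed plants showed from 10 to 24 days. The 2 changes share the non-exposed libraries of 10 days, which alone gave a covariance of at most 0.132 in 100 simulations, against 0.718 observed. The observed correlation was 0.477, and the simulated one, which holds noise only, 0.546. Without the library that stood apart, the covariance exceeded the simulated one by 0.578. The excess does not decide the hypothesis, because the simulation gave all groups equal means. Any real difference of the non-exposed plants of 10 days from the 2 other groups gives an excess, with or without such a shift. A peculiarity common to all non-exposed libraries of 10 days could give the same covariance. The 3 shared libraries were too few to split into sets of at least 2, so part of the excess may come from them.

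Another hypothesis was that neighbours in the identifier numbering respond together outside the runs. The correlation of the 24-day log2 fold change between adjacent tested identifiers, across 24914 pairs of genes, was 0.105, against at most 0.0194 in 1000 shuffles. It was 0.0471 for identifiers 2 places apart, 0.0127 at 5 places and -0.0117 at 10 places. Shared reads between similar neighbouring genes could give this as well as joint regulation, and these were not separated.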
